A study of Mus musculus with 12 samples.

How the data were processed

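Per the labels, RNA came from distal colorectal epithelium of female BALB/c mice on day 100, with 3 arrays in each of 4 groups. Per the labels' protocols, AOM, DSS and control epithelium was scraped off with a slide into Trizol, whereas AOM/DSS neoplasms were clipped and kept in RNA storage solution. The AOM dose also differed between groups: 12.5 mg/kg on day 1 in the AOM/DSS group and 10 mg/kg weekly, 6 times, in the AOM group, per the labels. Total RNA was purified with miRNeasy columns, checked for integrity, and amplified and labelled with Cy3 by the Low Input Quick Amp kit, per the labels' protocols. Whether the 3 replicates of a group are separate mice is not given in the sources used here.

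The deposited scanner files hold one-colour intensity values written by Agilent Feature Extraction 10.7.3.1, per the file headers, and 10.7 per the submitters' processing notes. In them the processed signal is an intensity after removal of background and spatial trend, floored above 0 and not normalized between arrays, per the file headers. Median spot and median local background intensity are raw values, per the file headers, and mean spot signal is not given in the sources used here. The deposited series matrix holds log2 values whose sorted columns are equal within 0.000945, with a column median of 6.174, so they were quantile normalized by the authors; the software is not given in the sources used here. Correlation with the log2 processed signal of the same array ran from 0.995 to 1.000.

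Each array has 45018 spots, of which 41174 are non-control probes. Gene symbols came from the RefSeq accession of the probe: 27198 probes carried a symbol (18539 genes) and 13976 did not, the latter kept under their own identifiers. Intensity was taken to log2 and each array's 75th percentile was subtracted. A probe was kept if it was well above background on all 3 arrays of at least 1 group, and each gene was represented by its probe with the highest mean over the 12 arrays. This left 18917 genes, 13492 of them with a symbol.

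Group means were fitted with lmFit of limma 3.58.1 in R 4.3.3, without an intercept, and contrasts were tested with limma's moderated t test (eBayes, 8 residual and 2.63 prior degrees of freedom). P-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. The moderated F test gave genes with any group difference. These p-values measure only the spread between these samples, which may be technical. For a gene well above background on no array of the lower group, a lower bound is given, "at least" so many fold. It sets each of those arrays at the signal of the dimmest probe that passed there, or at the gene's own signal if higher. The bound is approximate, since it leaves out the error of the group means.

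The design, the comparisons, the alternatives, the gene lists and the rule for naming genes were set before the data were examined. Named genes are, per comparison, the 10 largest rises and 10 largest falls among called genes with non-overlapping values, well above background on all 3 arrays of the higher group, unsaturated, and carrying a gene name. Where fewer passed, all that passed are named. Genes called in all 3 AOM/DSS comparisons were ranked by their smallest change. Up to 4 called members with the largest change were taken from each list, or up to 2 with the smallest p where none was called, and a fixed panel of 23 genes was followed in every comparison. Not every gene that meets the rule is printed.

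There were 33 gene lists, 20 of programmes and 13 of cell types, written from general knowledge; 438 of their 455 members are on the array. The red blood cell list had fewer than 3 measured members and was not tested, which left 32 lists and 192 tests over 6 comparisons. Lists were tested with limma camera at a preset correlation of 0.01, adjusted by Benjamini-Hochberg over all 192 tests. Camera with an estimated correlation and fry were the alternatives. Member counts are given over all genes tested and adjusted over the list alone. List medians are also given with dim members set at their bound where that moves the median by over 0.1.

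The file headers show 3 slides of 4 arrays. One slide held AOM replicates 1 and 2 with AOM/DSS replicates 1 and 2, another AOM replicate 3 with the 3 DSS arrays, and the last AOM/DSS replicate 3 with the 3 control arrays. Slide was not in the fitted model and was added as a fixed block as an alternative. In that fit, AOM/DSS against AOM, AOM/DSS against control and DSS against AOM are each compared within 1 slide, and the other contrasts are chained across slides. Replicate numbers were not used to pair arrays, and a fit with replicate number as a block was run as an alternative.

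The alternatives set beforehand were normexp background correction with an offset of 50, median scaling, quantile normalization, the authors' series matrix values, no filter, a filter on all 12 arrays, and the mean of a gene's probes. A variance trend with a robust prior, array weights, slide block, replicate block, a 2-fold threshold, adjusted p under 0.01, fits of 2 groups only and fits without each array in turn were also set beforehand. Normexp had been planned on mean spot intensity and was run on the median, since the mean is not given in the sources used here. On DSS replicate 2 and control replicates 1 and 2 a few spots with local background far above their signal governed that fit, and its maximum likelihood variant and removal of spots the scanner marked as uneven did not help. It was therefore also run without spots over 50 units below their background. That alternative, fits on named genes only, fits with the median of cDNA clone probes as a covariate, and fits without 2 pairs of arrays were chosen after seeing the data.

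The AOM and DSS effects share the control arrays, so their correlation and covariance were set beside 100 simulations of unchanged groups against the same controls. Each gene was drawn independently in those simulations. In a self-test on simulated values with the same spread, 100 genes were changed by 1 log2 unit and 100 by 2. The pipeline recovered 11% and 60% of them in AOM/DSS against control and 15% and 60% in DSS against control, with false calls at 5.33% and 9.64% of calls. The self-test made 75 and 83 calls in these comparisons, against 6567 and 62 in the data. With so few changed genes its Benjamini-Hochberg cutoff was stricter than that of AOM/DSS against control. Its recovery therefore does not measure that of comparisons with far more calls. No array was left out, and the companion small RNA data named in the series title were not analysed here. The sources used here give no lesion counts or histology for the mice.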

Results

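Messenger RNA was measured on one-colour mouse oligonucleotide arrays in distal colorectal epithelium of female BALB/c mice on day 100. The 12 arrays form 4 groups of 3. AOM/DSS arrays hold neoplasms of mice given azoxymethane (AOM, a colon carcinogen) and dextran sulfate sodium (DSS, which damages the epithelium and causes colitis). The others hold scraped epithelium after AOM alone, after DSS alone, or without treatment (control). The 75th percentile of processed intensity was 1115 to 1185 on the AOM/DSS arrays and 393 to 694 on the other 9. Between 62.6 and 66.2% of probes were well above background on the AOM/DSS arrays and 52.1 to 59.3% on the others, and no spot was saturated. AOM/DSS tissue differed from the other groups in collection, storage and AOM dose as well as in disease. The labels do not say whether replicates are separate mice.

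The 4 groups differed in 9958 of 18917 genes (limma moderated F test, Benjamini-Hochberg adjusted p under 0.05, n = 3 arrays per group). The count was 5921 without AOM/DSS replicate 1 and 6520 without AOM/DSS replicate 2. The first principal component held 39.9% of the variance and set the AOM/DSS arrays (122 to 129) apart from the rest (-79.8 to -5.01), and the next held 32.3%. AOM replicate 1 and DSS replicate 2 correlated best with each other (0.978), as did DSS replicate 1 and control replicate 3 (0.970), and the other arrays were each nearest to one of their own group. With slide as a block, 2488 genes were called.

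**Figure D1:**
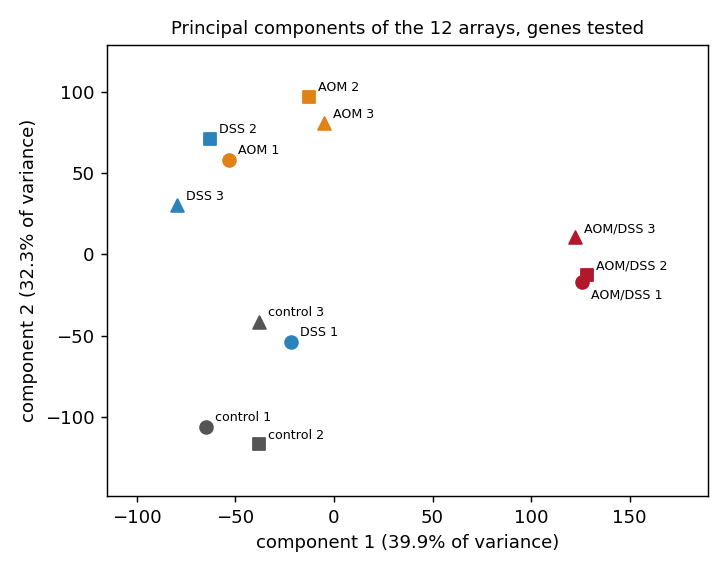
Principal components 1 (39.9% of the variance) and 2 (32.3%) of log2 values over 18917 genes, 1 point per array, 3 arrays per group. The AOM/DSS arrays lie together at 122 to 129 on component 1, and AOM replicate 1, DSS replicate 1 and control replicate 3 lie apart from the others of their groups.

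Matrilysin (Mmp7), a metalloproteinase made by Paneth cells and intestinal adenomas, was at least 1209-fold higher in AOM/DSS neoplasms than in control epithelium (fitted log2 difference 11.71 ± 0.84 SE, limma adjusted p = 1.9e-05, n = 3 per group). The calprotectin subunits S100a9 and S100a8, abundant in neutrophils, rose by 8.59 ± 0.78 and 8.20 ± 0.97 log2 units, and the neutrophil-attracting chemokine Cxcl5 by at least 99.2-fold. The chloride exchanger Slc26a3 and the water channel Aqp8, which mark mature colonocytes, fell (log2 difference -9.51 ± 0.94 and -9.41 ± 0.96). The L-cell hormone gene Gcg fell by 7.18 ± 0.87. In all, 6567 of 18917 genes were called, 3264 higher and 3303 lower (limma moderated test, Benjamini-Hochberg adjusted p under 0.05). Without control replicate 1 it was 4293. The higher share was 49.7%, and 39.1% of 5803 calls under median scaling. With slide as a block, which sets AOM/DSS replicate 3 against the 3 controls on its slide, 2204 genes were called, 931 higher and 1273 lower.

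Several of the largest rises were genes known to act on Wnt signalling, a grouping that was not tested as a list of its own. Nkd1, a dishevelled-binding inhibitor, rose by 8.21 ± 1.11 log2 units (limma adjusted p = 0.00046, 8.11 with slide as a block), Wif1, which binds Wnt ligands, by 7.89 ± 0.97 (7.67 with the block), and Dkk2, a ligand of Wnt co-receptors, by at least 55.0-fold. Notum, which strips lipid from Wnt ligands, rose at least 53.8-fold. Of 21 Wnt targets and crypt stem cell genes, 17 rose and 4 did not pass over all genes tested. Adjusted over the list alone, 18 rose. Axin2, a feedback inhibitor, rose by 2.96 ± 0.68 and the stem cell receptor Lgr5 by 3.55 ± 0.91, while Sox9, a crypt transcription factor, was at 0.65 ± 0.43 (limma adjusted p = 0.27). The list median was 2.74 log2 units, 2.19 with dim members at their bound and 2.40 with slide as a block. It was called (camera adjusted p = 4.3e-08, and adjusted p = 0.491 with an estimated correlation).

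Genes of differentiated epithelium were low in the neoplasms. Of 21 absorptive colonocyte genes, 18 fell and 3 did not pass over all genes tested (19 fell and 1 rose adjusted over the list alone). The membrane carbonic anhydrase Car4 fell by 8.71 ± 0.83 log2 units, while Car1, the cytosolic form, was at 1.06 ± 0.39 (limma adjusted p = 0.056). All 14 goblet cell genes fell, over all genes tested and adjusted over the list alone, among them the resistin-like gene Retnlb by 8.42 ± 0.96 and the mucin Muc2 by 3.94 ± 0.59. Of 11 enteroendocrine genes, 10 fell and 1 did not pass (10 adjusted over the list alone), among them Insl5 by 6.65 ± 0.64 and Pyy by 5.25 ± 0.44, both made in L cells. The 3 list medians were -3.33, -3.66 and -4.34 log2 units, the first and last -3.16 and -3.01 with dim members at their bound, and -3.72, -4.80 and -4.91 with slide as a block. Camera adjusted p = 4.9e-10, 1.3e-08 and 1e-07, and for each list adjusted p = 0.491 with an estimated correlation. Other large falls were Hao2, a peroxisomal oxidase (-9.34 ± 1.04), Cyp2f2, a cytochrome P450 (-8.72 ± 0.99), Mptx1, a mucosal pentraxin (-8.53 ± 1.20), and Sycn, a protein of secretory granules (-8.24 ± 0.75).

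Inflammatory and matrix genes were high. Of 17 cytokine and chemokine genes, 13 rose and 4 did not pass over all genes tested (14 rose adjusted over the list alone), including interleukin Il1b by 5.05 ± 0.78 log2 units and Cxcl2, which attracts neutrophils, by at least 10.4-fold. Of 14 matrix metalloproteinase and remodelling genes, 13 rose and 1 did not pass (13 adjusted over the list alone), including stromelysin Mmp10 by 6.40 ± 0.91. The medians were 3.54 and 3.48, 2.99 and 3.00 at the bound, and 3.80 and 4.21 with slide as a block (camera adjusted p = 4.3e-07 and 1.8e-06, adjusted p = 0.491 with an estimated correlation for both). Of 12 repair epithelium genes, 7 rose and 5 did not pass (7 adjusted over the list alone; camera adjusted p = 0.0074, adjusted p = 0.645 with an estimated correlation). Lcn2, an iron-chelating lipocalin, was at least 112-fold higher. The 11 antimicrobial genes, 6 higher and 3 lower over all genes tested and adjusted over the list alone, were not called as a list (camera adjusted p = 0.46).

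Of 23 cell cycle genes, 18 rose, 1 fell and 4 did not pass over all genes tested (19 rose and 1 fell adjusted over the list alone). Examples are the mitotic kinase Cdk1, up by 2.62 ± 0.42 log2 units, and its cyclin Ccnb1 by 2.55 ± 0.40. The median was 1.76, and 2.07 with slide as a block (camera adjusted p = 5.5e-07, adjusted p = 0.645 with an estimated correlation). Mitochondrial genes went the other way: 13 of 16 oxidative phosphorylation genes fell, 1 rose and 2 did not pass over all genes tested (the same counts adjusted over the list alone). The cytochrome oxidase subunit Cox6c fell by 1.64 ± 0.27. Of 16 fatty acid oxidation genes, 12 fell, 2 rose and 2 did not pass (13 fell and 2 rose adjusted over the list alone), including the nuclear receptor Ppara by 2.74 ± 0.38. Of 16 xenobiotic metabolism genes, 9 fell, 3 rose and 4 did not pass (10 and 3 adjusted over the list alone), with Cyp3a13, a drug-metabolising P450, down by 5.79 ± 0.58. The 3 medians were -0.89, -1.23 and -1.66, and -0.70, -1.18 and -1.47 with slide as a block. Camera adjusted p = 0.00018, 0.00012 and 0.0018, with adjusted p = 0.645, 0.491 and 0.491 with an estimated correlation.

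Marker genes of other cell types also differed. All 9 neutrophil markers rose, over all genes tested and adjusted over the list alone (median 3.85 log2 units, 3.58 at the bound, 4.57 with slide as a block). Of 11 macrophage markers 8 rose and 3 did not pass (11 adjusted over the list alone), with arginase Arg1 at least 23.4-fold higher. Camera adjusted p = 1.3e-06 and 0.00062, with adjusted p = 0.491 and 0.645 with an estimated correlation. Fibroblast and collagen markers gave 7 rises, 1 fall and 6 not passing among 14 (10 and 1 adjusted over the list alone), such as collagen Col1a1 by 3.04 ± 0.71, and endothelial markers 4 rises and 6 not passing among 10 (4 adjusted over the list alone). Camera adjusted p = 0.025 and 0.01, with adjusted p = 0.748 and 0.708 with an estimated correlation, and with slide as a block the fibroblast list was no longer called (camera adjusted p = 0.087). Fibroblast scores on control replicates 1 and 2 were -1.74 and -2.41, against 0.79 on control replicate 3 and 0.14 to 0.67 on the AOM/DSS arrays. Endothelial scores were -2.25 and -1.99 on control replicates 1 and 2, 0.44 on control replicate 3 and 0.33 to 0.46 on the AOM/DSS arrays. Both rises therefore rest on control replicates 1 and 2. Of 9 B and plasma cell markers 3 fell and 6 did not pass (5 fell adjusted over the list alone), including the B cell marker Ms4a1 by 4.24 ± 1.18. Camera gave adjusted p = 0.02 for them, and adjusted p = 0.708 with an estimated correlation; with slide as a block their median went from -2.35 to -1.35 and the call ended (camera adjusted p = 0.12). Of 10 epithelial markers 6 fell and 4 did not pass (6 adjusted over the list alone; camera adjusted p = 0.0098, adjusted p = 0.708 with an estimated correlation). Epcam, an epithelial adhesion molecule, was at -0.52 ± 0.26 (limma adjusted p = 0.14). Not called as lists by camera were smooth muscle (adjusted p = 0.37), T cells (0.89), mast cells (0.75), enteric neurons and glia (0.29), adipocytes (0.5) and squamous epithelium (0.74).

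Elastase Cela3b, a digestive enzyme of the exocrine pancreas, was at least 401-fold lower in AOM/DSS than control arrays (fitted log2 difference -10.34 ± 2.16, and -8.31 without control replicate 3), with control values of 3.58 ± 4.03 (mean ± SD, n = 3). The median of 22 pancreatic genes was 6.02 on control replicate 3, 1.09 and -0.83 on the other controls, 3.05 on DSS replicate 1, and -3.09 to -2.14 on the other arrays outside the controls. Also measured were 3 lists with median and mean below 0.5 log2 units in size and no camera call: p53 targets (adjusted p = 0.63), hypoxia and glycolysis (0.2) and interferon response genes (0.37), in which Irf7, an interferon-induced transcription factor, fell by 1.91 ± 0.36. MHC class II genes (camera adjusted p = 0.075), tuft cell genes (0.39), posterior Hox genes (0.83), and immediate early and heat shock genes (0.56) were not called either. The prostaglandin list had a median of 0.14 and a mean of -0.04 and camera put it upward (adjusted p = 0.95), with the prostaglandin-degrading enzyme Hpgd down by 4.22 ± 0.54.

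**Figure D2:**
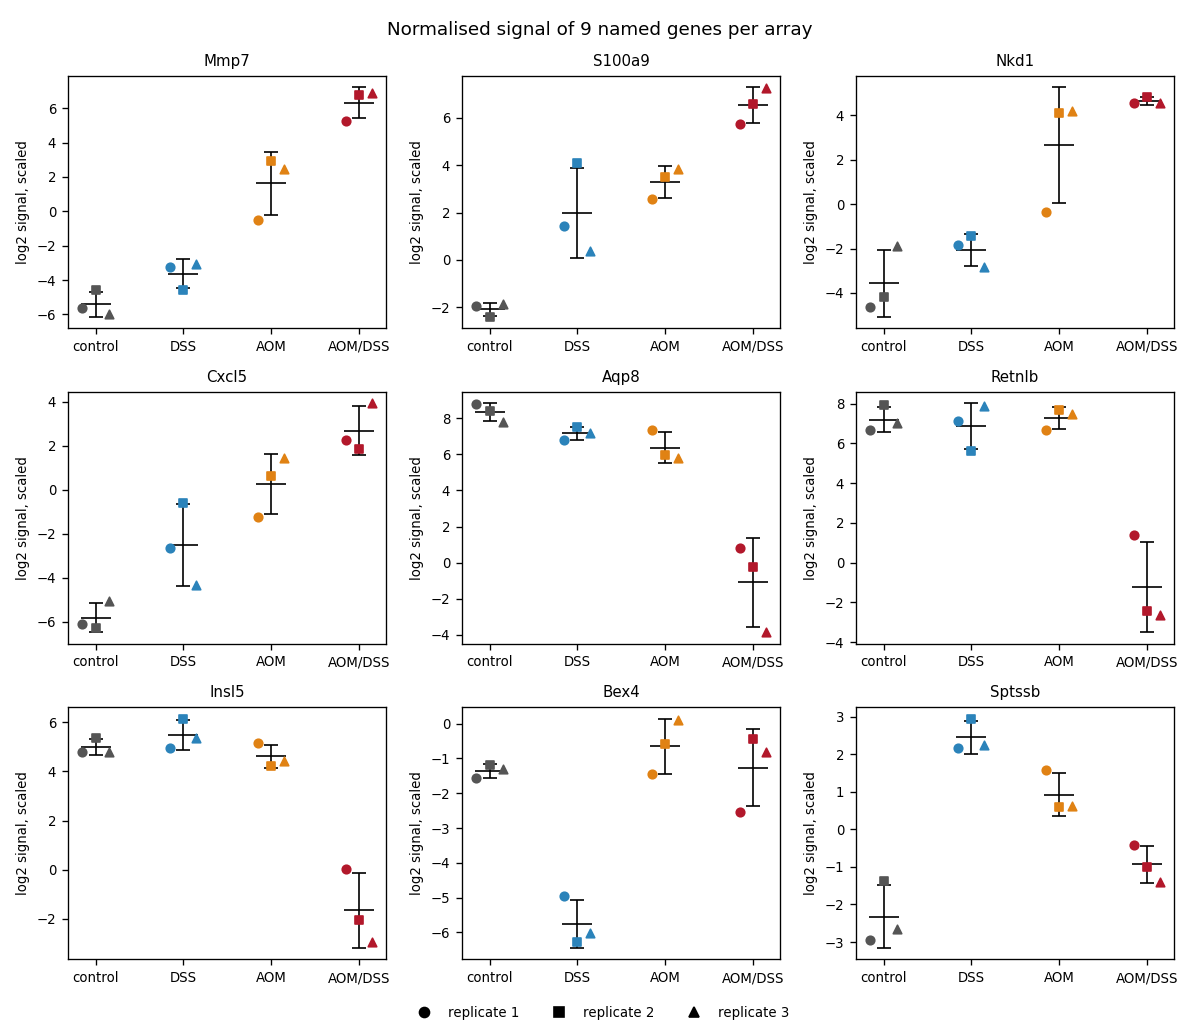
Log2 value minus the array's 75th percentile (y axis, log2 units) of 9 genes in control, AOM, DSS and AOM/DSS arrays; points are arrays and bars mean ± SD, n = 3. Mmp7 is at least 10.24 log2 units higher in AOM/DSS than in control, and the difference for Aqp8 is -9.41.

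**Figure D3:**
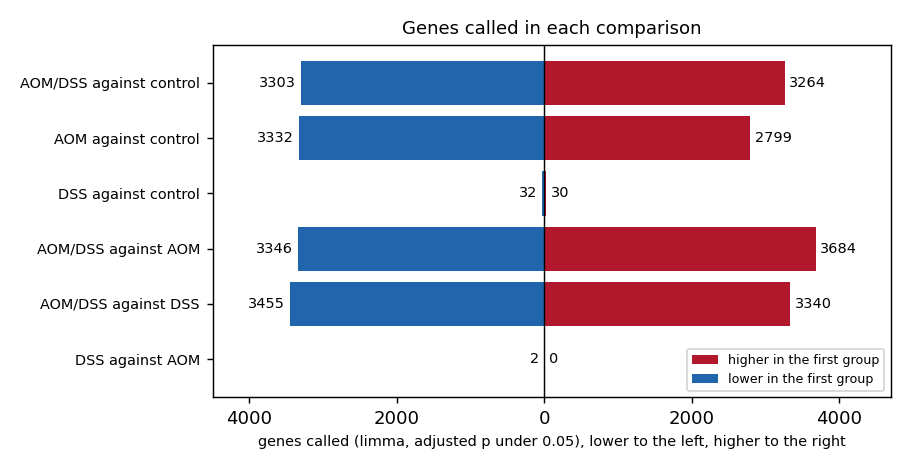
Genes called lower (to the left) and higher (to the right; x axis, number of genes) in each of 6 comparisons (y axis) at a limma adjusted p under 0.05, n = 3 arrays per group. AOM/DSS against control gave 6567 calls and DSS against AOM gave 2.

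Epithelium from mice given AOM alone also carried high Mmp7 (at least 47.3-fold above control, fitted log2 difference 7.04 ± 0.84, limma adjusted p = 0.0028, n = 3 per group). The Wnt inhibitor Nkd1 was up by 6.22 ± 1.11 log2 units and the ligand gene Wnt10a by 5.84 ± 0.73 (7.72 and 6.84 without AOM replicate 1), and the serine protease gene Prss56 at least 27.4-fold. Hair keratins Krt36 and Krt35 were at least 75.1-fold and 15.3-fold higher, and the antibacterial lectin Reg3g rose by 6.03 ± 1.22. In all, 6131 genes were called, 2799 higher and 3332 lower (limma, Benjamini-Hochberg adjusted p under 0.05). The higher share was 45.7%, and it was 53.7% of 5562 calls under median scaling, 57.1% of 1870 with normexp on all spots and 58.4% of 4350 on named genes alone. The count was 1960, 3565, 2298 and 2759 without AOM replicate 2, AOM replicate 3, control replicate 1 and control replicate 2. AOM and control arrays share no slide. With slide as a block 4 genes were called, 2 higher and 2 lower, so most values below carry an adjusted p above 0.05 in that fit. Genes without a name had a median difference of -0.62, and named genes one of 0.16; with the median of cDNA clone probes as a covariate, tested on named genes, 1 gene was called. In that fit 4140 of the 4146 named genes called here kept their sign; the covariate itself differs between these groups.

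Of the 21 Wnt targets and crypt stem cell genes, 11 rose and 10 did not pass over all genes tested (13 rose adjusted over the list alone), including Sp5, a transcription factor induced by Wnt (at least 23.6-fold), and Notum (at least 12.6-fold). Axin2 was at 1.52 ± 0.68 and Lgr5 at 1.14 ± 0.91 (limma adjusted p = 0.11 and 0.35). The list median was 1.61, and 1.00 with slide as a block (camera adjusted p = 8.1e-06, adjusted p = 0.645 with an estimated correlation). Its score was -0.51, 1.46 and 1.42 on AOM replicates 1, 2 and 3. Of 23 cell cycle genes, 19 rose and 4 did not pass over all genes tested (19 adjusted over the list alone), with the mitotic kinase Plk1 up by 2.50 ± 0.39. The median was 1.76, and 2.40 with slide as a block (camera adjusted p = 1.4e-08, adjusted p = 0.645 with an estimated correlation).

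Inflammation genes were also higher after AOM. Of 17 cytokine genes 11 rose and 6 did not pass over all genes tested (11 adjusted over the list alone), with Cxcl5 at least 18.5-fold and Il1b up by 3.45 ± 0.78 log2 units. Of 14 metalloproteinase and remodelling genes 10 rose and 4 did not pass (12 adjusted over the list alone), with stromelysin Mmp3 up by 4.27 ± 1.38. The medians were 2.40 and 3.24, 2.03 and 2.92 at the bound, and 2.92 and 3.73 with slide as a block. Camera adjusted p = 4.4e-05 and 9.1e-06, with adjusted p = 0.645 and 0.491 with an estimated correlation. Of 9 neutrophil markers 8 rose and 1 did not pass (8 adjusted over the list alone), with S100a9 up by 5.36 ± 0.78, a list median of 3.28, and 2.06 at the bound. Of 11 macrophage markers 8 rose and 3 did not pass (9 adjusted over the list alone), including the complement gene C1qa by 2.82 ± 0.71. Camera adjusted p = 1.1e-05 and 0.00015 for these 2 lists, with adjusted p = 0.491 and 0.645 with an estimated correlation. Among 12 repair genes 4 rose and 8 did not pass (4 adjusted over the list alone; median 0.69, and 1.05 at the bound). Among 7 mast cell markers 3 rose and 4 did not pass (4 adjusted over the list alone), with the chymase Cma1 up by 2.01 ± 0.38. Camera gave adjusted p = 0.029 and 0.021, and adjusted p = 0.645 with an estimated correlation for both. The mast cell median went from 2.01 to 0.59 with slide as a block and its call ended (camera adjusted p = 0.32).

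Over all genes tested after AOM, 6 of 14 fibroblast markers rose, 1 fell and 7 did not pass. Of 12 smooth muscle markers 2 rose and 10 did not pass, and of 10 endothelial markers 5 rose and 5 did not pass. Adjusted over the list alone there were 9 rises and 1 fall, 1 rise and 7 rises. Matrix glycoprotein Sparc rose by 3.54 ± 0.82 and endothelial cadherin Cdh5 by 3.00 ± 0.75 log2 units. Camera adjusted p = 0.0093, 0.0057 and 0.0023, with adjusted p = 0.708, 0.704 and 0.704 with an estimated correlation. The fibroblast and smooth muscle lists were no longer called with slide as a block (camera adjusted p = 0.089 and 0.063). Control replicates 1 and 2 carried low endothelial scores (-2.25 and -1.99, against 0.44 on control replicate 3), and control replicate 3 scored 0.79 for fibroblast and 0.72 for smooth muscle markers, against 0.23 to 0.59 and 0.56 to 0.94 on the AOM arrays.

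Fewer differentiation genes were called after AOM. Of 21 absorptive genes 7 fell and 14 did not pass over all genes tested (7 adjusted over the list alone), including Slc26a3 by 3.38 ± 0.94 log2 units, which stayed called with slide as a block (-7.61, limma adjusted p = 0.034). The monocarboxylate transporter Slc5a8 fell by 3.14 ± 0.34, while Aqp8 was at -1.95 ± 0.96 (limma adjusted p = 0.13). Of 14 goblet cell genes 2 fell and 12 did not pass (1 adjusted over the list alone), among them the secretory transcription factor Atoh1 by 1.28 ± 0.33. Of 16 fatty acid oxidation genes 6 fell, 1 rose and 9 did not pass (7 and 1 adjusted over the list alone), including the coactivator Ppargc1a by 2.52 ± 0.35. The medians were -1.01, -0.90 and -0.57, and -1.65, -2.19 and -0.50 with slide as a block. Camera adjusted p = 0.0014, 0.038 and 0.012, with adjusted p = 0.645, 0.72 and 0.645 with an estimated correlation. Of 11 enteroendocrine genes 1 rose, the peptide hormone gene Cck by 2.18 ± 0.28 (1 adjusted over the list alone), and 10 did not pass. The 10 epithelial markers, with 1 rise, had a median of -0.03 and a mean of 0.19 and camera put them upward (adjusted p = 0.88). The adipocyte list had a median of 0.35 and a mean of -0.11 (upward, adjusted p = 0.88).

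Of the 10 largest falls after AOM, 7 were genes abundant in the exocrine pancreas: Cela3b (at least 264-fold lower), carboxypeptidase Cpa1 (at least 165-fold), lipase Pnlip (at least 66.3-fold), amylases Amy2a5 (at least 46.7-fold) and Amy1 (-7.21 ± 2.05 log2 units), and the lectins Reg1 (at least 44-fold) and Reg2 (at least 19.5-fold). These genes varied among the controls, as given above. Without control replicate 3 the fitted difference of Cela3b was -7.95, against -9.98, and Pnlip, Amy2a5, Amy1 and Reg1 were no longer called (limma adjusted p = 0.071, 0.097, 0.061 and 0.11). These 4 also lost their call without AOM replicate 1, 2 or 3 or control replicate 1, and Cpa1 and Reg2 without AOM replicate 2 or control replicate 1. The other falls were the protease inhibitor Spink5 (-4.52 ± 0.69), the splicing factor Srrm3 (-4.79 ± 1.13, with its other probe at 0.92) and the P450 gene Cyp2c39 (at least 6.38-fold lower).

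DSS alone left few genes called against control. Khdc1a, a KH-domain gene known from oocytes, rose by 5.92 ± 0.68 log2 units (limma adjusted p = 0.0098, n = 3 per group) and its relative Khdc1c at least 3.58-fold (paralogs that a probe may not tell apart). Sptssb, a subunit of the enzyme that starts sphingolipid synthesis, rose by 4.76 ± 0.45 (limma adjusted p = 0.0054). The whey acidic protein gene Wfdc18 rose by 4.16 ± 0.70, the proprotein convertase Pcsk5 by 4.15 ± 0.44, the ubiquitin ligase Rnf183 by 3.03 ± 0.33, and the intestinal homeobox gene Isx at least 5.19-fold. Falls included Spink5 (-4.58 ± 0.69), Bex4, a small regulator of tubulin (at least 6.67-fold), the sugar-phosphate exchanger Slc37a2 (-3.28 ± 0.30), the chromatin protein Hmga2 (-3.14 ± 0.47) and the fructose transporter Slc2a5 (-3.11 ± 0.39). Falls also included the circadian repressor Ciart at least 6.67-fold, the clock-output factor Dbp by 2.85 ± 0.40 and the period gene Per3 by 2.76 ± 0.45.

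In all, 62 genes were called for DSS against control, 30 higher and 32 lower (limma, Benjamini-Hochberg adjusted p under 0.05), and 3989 had an unadjusted p under 0.05. The count was 3181, 1 and 8 without DSS replicates 1, 2 and 3, and 10, 23 and 1333 without control replicates 1, 2 and 3. Of these calls 31.6% were higher without DSS replicate 1 and 82.0% without control replicate 3. It was 32 and 34 without AOM replicates 2 and 3, and 40 without AOM/DSS replicate 2. DSS and control arrays share no slide. With slide as a block 2 genes were called. Of the 62 genes called here, 0 kept their call in that fit, and 62 kept their sign. Without DSS replicate 1 and control replicate 3 together, 4277 genes were called.

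After DSS, 0 of 9 neutrophil and 0 of 11 macrophage markers passed over all genes tested, and 7 and 10 rose adjusted over the list alone. The list medians were 1.95 (1.09 at the bound) and 2.21 log2 units (2.62 and 2.96 with slide as a block). S100a9 was at 4.04 ± 0.78 and C1qb, a complement gene of macrophages, at 2.11 ± 0.54 (limma adjusted p = 0.063 and 0.11). Camera called both lists (adjusted p = 1.8e-06 and 1e-07, adjusted p = 0.491 with an estimated correlation for both). None of 17 cytokine genes, 14 metalloproteinase genes, 14 fibroblast markers and 10 endothelial markers passed over all genes tested, and 4 of each rose adjusted over the list alone. Examples are the inhibitor of metalloproteinases Timp1 (1.90 ± 0.51) and the tumour necrosis factor gene Tnf (1.84 ± 0.37). The 4 medians were 1.17, 1.83 (1.70 at the bound), 1.56 and 1.64. Camera called each (adjusted p = 0.00012, 4.4e-05, 0.00026 and 0.00014, adjusted p = 0.645, 0.566, 0.645 and 0.645 with an estimated correlation). The macrophage score was -1.75, -2.91 and -0.35 on control replicates 1, 2 and 3 and 0.19, 1.17 and 0.01 on the DSS arrays. For fibroblast markers it was -1.74, -2.41 and 0.79 against 0.40, 0.72 and -0.09. For endothelial markers it was -2.25, -1.99 and 0.44 against 0.37, 0.84 and -0.13.

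The cell cycle, smooth muscle, T cell, B and plasma cell, immediate early and goblet lists had 0 members passing over all genes tested and 0 adjusted over the list alone after DSS. Their medians were 0.55, 1.10, 1.17, 1.90, 0.51 and -0.47. Camera called each of them (adjusted p = 7.9e-05, 0.00062, 0.0074, 0.0011, 0.017 and 0.048, with adjusted p = 0.708, 0.645, 0.708, 0.645, 0.706 and 0.742 with an estimated correlation). The smooth muscle score was -0.44, -1.63 and 0.72 on control replicates 1, 2 and 3 and 0.37, 1.03 and 0.33 on the DSS arrays. Cell cycle scores were -1.58, -0.71 and -0.59 against -0.75, 0.22 and -0.35. For goblet genes they were 1.47, 1.81 and 0.99 against 0.51, 0.45 and 1.47. Immediate early scores were 0.10, -0.61 and -0.37 against -0.43, 0.64 and 0.68. Scores of these lists overlapped between the groups, and those of the T cell and the B and plasma cell lists did not. The smooth muscle and immediate early lists were no longer called with slide as a block (camera adjusted p = 0.059 and 0.85) and the immediate early median turned to -0.21. The cell cycle, T cell, B and plasma cell and goblet medians were 1.24, 3.39, 5.65 and -1.71 in that fit. Of 11 enteroendocrine genes Cck rose by 2.31 ± 0.28 and 10 did not pass (1 adjusted over the list alone; median 0.44, -0.04 with slide as a block; camera adjusted p = 0.0093, 0.9 with the block, adjusted p = 0.645 with an estimated correlation). The 21 Wnt genes had a median of 0.02 and camera adjusted p = 0.86, and -1.30 with slide as a block (camera adjusted p = 0.0033 in that fit). Median, mean and camera direction differed in sign for interferon (-0.02, -0.00, up), p53 (-0.11, 0.04, down), oxidative phosphorylation (0.00, -0.00, down) and adipocyte genes (0.04, -0.53, down), none of them called.

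**Figure D4:**
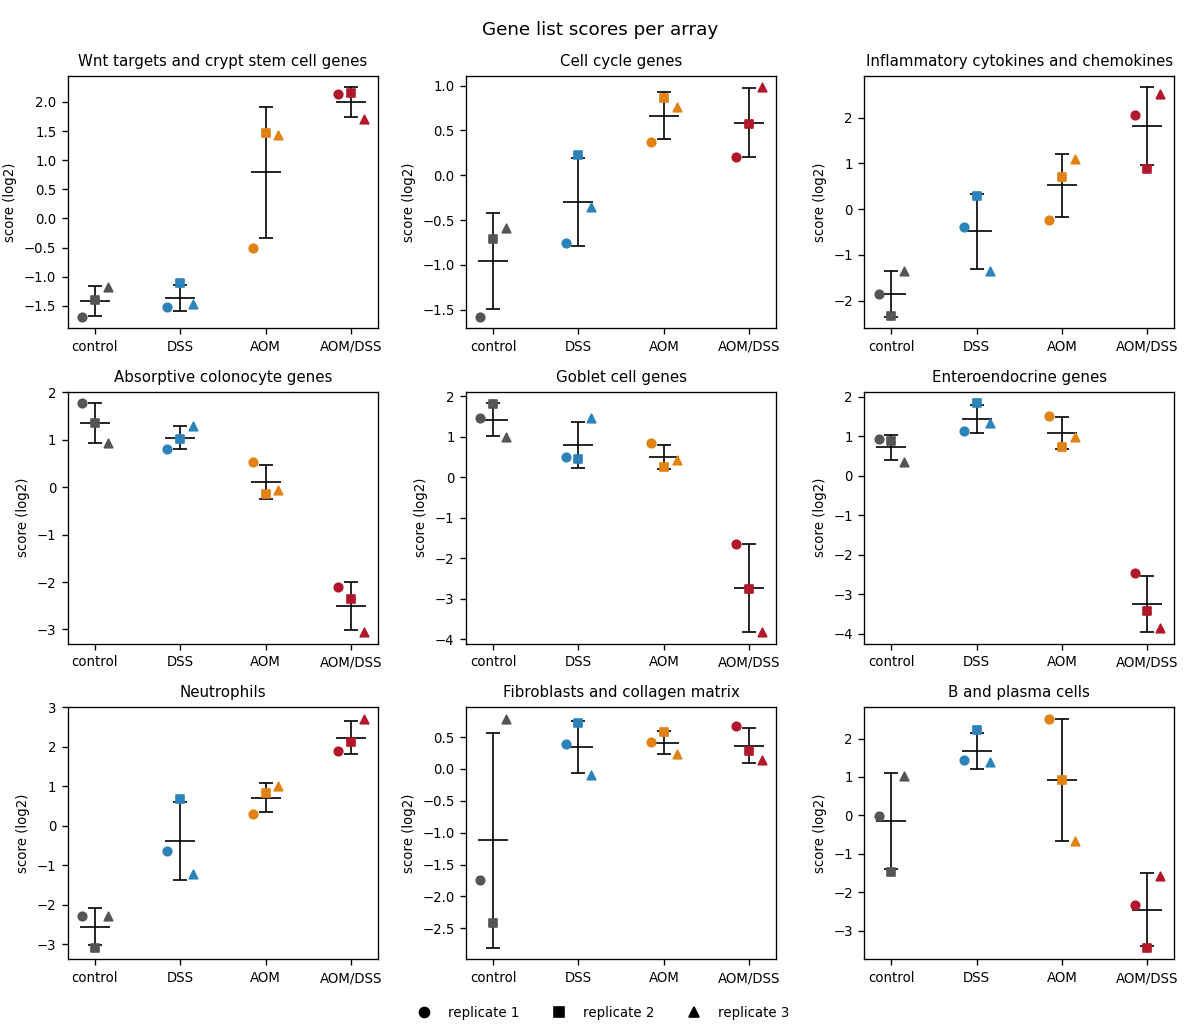
List score (y axis, mean over members of log2 value minus the gene's mean over 12 arrays) of 9 gene lists in control, AOM, DSS and AOM/DSS arrays; points are arrays and bars mean ± SD, n = 3. The Wnt score is -0.51 on AOM replicate 1, 1.46 and 1.42 on the other AOM arrays, and 1.71 to 2.14 on AOM/DSS arrays.

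Against epithelium after AOM alone, secretory and absorptive genes were lower in the neoplasms: Retnlb (log2 difference -8.50 ± 0.96), Aqp8 (-7.45 ± 0.96) and Gcg (-6.87 ± 0.87) fell (limma adjusted p = 0.00066, 0.0013 and 0.0012, n = 3 per group). Within the slide that holds AOM replicates 1 and 2 beside AOM/DSS replicates 1 and 2, the values were -7.68, -6.36 and -6.23. Rises included Mmp7 (4.68 ± 0.84, 4.81 within the slide), the alpha-defensin Defa21 (5.99 ± 1.34; near-identical paralogs make its identity uncertain), the germ cell gene Tex15 (4.93 ± 0.76), the export pump Abcc2 (4.18 ± 0.70), the metabolic enzyme Aspa (3.99 ± 0.51) and the epithelial cytokine Il1f9 (at least 4.88-fold). In all, 7030 genes were called, 3684 higher and 3346 lower (limma, Benjamini-Hochberg adjusted p under 0.05). Within the slide 2850 were called, 1415 higher and 1435 lower. The count was 4435 and 4445 without AOM replicates 1 and 2 and 3365 and 4286 without AOM/DSS replicates 1 and 2. The higher share was 52.4%, and 33.7% of 7482 calls under median scaling. Unnamed genes had a median of 0.75 against -0.21 for named ones; tested alone, named genes gave 4618 calls, and 223 with the median of cDNA clone probes as a covariate (4499 of 4518 kept their sign).

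Against AOM, 14 of 21 absorptive genes fell and 7 did not pass over all genes tested (15 adjusted over the list alone). Among goblet genes 13 of 14 fell and 1 did not pass (14 alone), and 10 of 11 enteroendocrine genes fell and 1 did not pass (11 alone). Slc26a3 fell by 6.13 ± 0.94, the goblet lectin Zg16 by 5.43 ± 1.10 and Insl5 by 6.26 ± 0.64. Medians were -1.83, -2.69 and -4.67, and -1.75, -2.25 and -4.59 within the slide. Camera called all 3 (adjusted p = 5.1e-07, 6.1e-07 and 3.4e-09, adjusted p = 0.491, 0.544 and 0.491 with an estimated correlation). Over all genes tested 11 of 16 oxidative phosphorylation genes fell and 5 did not pass. Of 16 xenobiotic metabolism genes 10 fell, 1 rose and 5 did not pass, and of 16 fatty acid oxidation genes 6 fell and 10 did not pass. Adjusted over the list alone they gave 11 falls, 10 falls and 1 rise, and 7 falls and 1 rise. Examples are the respiratory chain gene Uqcrc1 (-1.61 ± 0.27), the glutathione transferase Gsta1 (-2.31 ± 0.23) and the carnitine transferase Cpt1a (-0.99 ± 0.24). Camera adjusted p = 0.00098, 0.0043 and 0.039, with adjusted p = 0.645, 0.491 and 0.645 with an estimated correlation, and within the slide the fatty acid oxidation list was no longer called (camera adjusted p = 0.059).

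Of 9 B and plasma cell markers 8 fell against AOM and 1 did not pass over all genes tested (9 adjusted over the list alone), including the receptor component Cd79b by 4.41 ± 0.98, and the IgM receptor gene Fcmr fell by 6.15 ± 1.14. The B and plasma cell score was 2.51, 0.93 and -0.66 on AOM replicates 1 to 3 and -3.45 to -1.57 on the AOM/DSS arrays. Of 12 smooth muscle markers 8 fell and 4 did not pass (9 adjusted over the list alone), including desmin (Des) by 3.25 ± 0.86. Medians were -3.42 and -1.53, and -4.82 and -1.61 within the slide. Both were called (camera adjusted p = 0.00067 and 0.00068, adjusted p = 0.645 with an estimated correlation for both). Over all genes tested 3 of 6 MHC class II genes fell and 3 did not pass, 3 of 14 immediate early genes fell and 11 did not pass, and 5 of 10 epithelial markers fell and 5 did not pass. Adjusted over the list alone 6, 3 and 5 fell. The class II activator Ciita fell by 1.71 ± 0.59, the early response gene Ier2 by 1.29 ± 0.25 and keratin Krt8 by 1.35 ± 0.28. Camera called the 3 lists (adjusted p = 0.039, 0.012 and 0.0029, adjusted p = 0.708, 0.688 and 0.688 with an estimated correlation). Within the slide the immediate early median was -0.61 and its call ended (camera adjusted p = 0.087).

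Of 21 Wnt and stem cell genes 4 rose against AOM and 17 did not pass over all genes tested (3 adjusted over the list alone), including the receptor Tnfrsf19 by 3.09 ± 0.79 and the ubiquitin ligase Znrf3 by 2.39 ± 0.51 (median 1.20, 1.67 within the slide). Of 17 cytokine genes 2 rose, Cxcl2 by 3.22 ± 0.84 and Il23a, which drives interleukin 17 responses, by 2.82 ± 0.79, and 15 did not pass (2 adjusted over the list alone). Camera adjusted p = 0.016 and 0.032, adjusted p = 0.708 with an estimated correlation for both, and within the slide the cytokine list was no longer called (camera adjusted p = 0.068). Of 23 cell cycle genes 2 rose and 21 did not pass (0 adjusted over the list alone; median -0.20, camera adjusted p = 0.81), with the proliferation antigen Mki67 up by 1.25 ± 0.43. With the median of cDNA clone probes as a covariate the cell cycle median was 0.65 (camera adjusted p = 0.00096). Hypoxia genes had a median of -0.20 and a mean of 0.00, and camera put them down (adjusted p = 0.88). Signs also differed for macrophage (median -0.23, mean 0.06, up, adjusted p = 0.99) and fibroblast markers (0.06, -0.05, up, adjusted p = 0.97), and the adipocyte median was -2.30, and -1.25 at the bound.

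Against epithelium after DSS alone, Mmp7 was higher by 9.94 ± 0.84 log2 units, Lgr5 by 6.68 ± 0.91, and Notum and Dkk2 at least 59.9-fold and 61.3-fold (limma adjusted p = 8.8e-05, 0.00083, 0.00058 and 0.00069, n = 3 per group). Defa21, Defa20 and Defa22, alpha-defensins whose identity is uncertain among paralogs, rose by at least 601-fold, 8.28 ± 1.65 and 8.11 ± 1.78 log2 units. Hao2 (-8.56 ± 1.04), Retnlb (-8.09 ± 0.96) and Cyp2c55, a colonic P450 (-7.29 ± 1.01), fell. In all, 6795 genes were called, 3340 higher and 3455 lower (limma, Benjamini-Hochberg adjusted p under 0.05). The count was 3875 and 4399 without AOM/DSS replicates 1 and 2, and 3318 without DSS replicate 3. The higher share was 49.2%, and 35.2% of 6305 calls under median scaling. These groups share no slide, and 437 genes were called with slide as a block, 201 higher and 236 lower.

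Of 21 Wnt and stem cell genes 16 rose against DSS and 5 did not pass over all genes tested (18 adjusted over the list alone; median 3.06, 2.60 at the bound, 4.77 with slide as a block). Absorptive (17 of 21 fell, 4 did not pass), goblet (13 of 14 fell, 1 did not pass) and enteroendocrine genes (11 of 11 fell) gave 19, 14 and 11 falls adjusted over the list alone. Their medians were -2.89, -2.96 and -4.80. Slc26a3 fell by 7.26 ± 0.94, the kallikrein Klk1 by 5.10 ± 0.63 and the granin Chgb by 5.74 ± 0.56. Camera adjusted p = 4.6e-08, 1.2e-10, 1.2e-07 and 1.6e-09, with adjusted p = 0.491 with an estimated correlation for all 4. Cytokine (9 of 17 rose, 8 did not pass), metalloproteinase (7 of 14 rose, 7 did not pass), cell cycle (10 of 23 rose, 1 fell, 12 did not pass) and neutrophil genes (7 of 9 rose, 2 did not pass) gave 11, 8, 10 (with 1 fall) and 8 rises adjusted over the list alone. Osteopontin (Spp1) rose by 4.70 ± 1.34, topoisomerase Top2a by 1.63 ± 0.33 and the chemokine receptor Cxcr2 by 2.67 ± 0.65. The medians were 2.07, 1.85 (1.06 at the bound), 0.87 and 2.49. Camera called all 4 (adjusted p = 0.00036, 0.0056, 0.00098 and 0.0015, adjusted p = 0.645, 0.645, 0.708 and 0.645 with an estimated correlation).

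All 9 B and plasma cell markers fell against DSS over all genes tested. Of 12 smooth muscle markers 6 fell and 6 did not pass, of 10 epithelial markers 7 fell and 3 did not pass, and of 6 MHC class II genes 3 fell and 3 did not pass. Adjusted over the list alone 9, 8, 7 and 6 fell. Calponin Cnn1 fell by 2.22 ± 0.77 and the invariant chain Cd74 by 1.44 ± 0.50. Each list was called (camera adjusted p = 0.00011, 0.0022, 0.0016 and 0.027, adjusted p = 0.645, 0.645, 0.645 and 0.708 with an estimated correlation). Oxidative phosphorylation (12 of 16 fell, 1 rose, 3 did not pass), fatty acid oxidation (12 of 16 fell, 1 rose, 3 did not pass), xenobiotic (9 of 16 fell, 2 rose, 5 did not pass) and immediate early genes (6 of 14 fell, 1 rose, 7 did not pass) gave 13, 12, 10 and 7 falls and 1, 1, 2 and 1 rises adjusted over the list alone. The sulfotransferase Sult1a1 fell by 3.67 ± 0.40 and the early response factor Fos by 2.07 ± 0.57. These lists were called as well (camera adjusted p = 0.00025, 0.00064, 0.0037 and 0.042, adjusted p = 0.645, 0.491, 0.491 and 0.708 with an estimated correlation). The immediate early median went from -0.90 to -0.17 with slide as a block and its call ended (camera adjusted p = 0.83), and the B and plasma cell, MHC class II and xenobiotic medians went from -4.21, -1.48 and -1.46 to -6.99, -2.74 and -2.25. Signs differed, without a call, for prostaglandin (median 0.17, mean -0.18, down), posterior Hox (0.19, -0.08, down) and macrophage genes (-0.07, 0.18, up), and the adipocyte median of -1.61 was 0 at the bound.

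In all 3 AOM/DSS comparisons, 2869 genes were called in the same direction, 1091 higher and 1778 lower (limma, Benjamini-Hochberg adjusted p under 0.05 in each). There were 1485 and 1822 without AOM/DSS replicates 1 and 2, and 265 with slide as a block. Besides Mmp7, Defa21 and Dkk2, the higher genes with the largest smallest change include the zinc finger gene Plagl1 (7.58 ± 0.98 against control, 3.87 ± 0.98 against AOM, and at least 7.01 against DSS), the glutamate-rich gene Erich3 (4.14 ± 1.29 against AOM) and the axon guidance ligand Sema3e (3.84 ± 0.74 against AOM). The lower genes include the matrix glycoprotein Thbs4 (-7.05 ± 0.75, -6.13 ± 0.75 and -6.53 ± 0.75) beside Insl5, Gcg, Retnlb, Mptx1, Car4, Cyp2f2, Hao2, Aqp8 and Slc26a3. The 3 comparisons share the AOM/DSS arrays.

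Tested directly, DSS against AOM, Bex4 was at least 10.8-fold lower after DSS (fitted log2 difference -5.10 ± 0.57). The ligand gene Wnt3 was at least 1.97-fold lower (-2.71 ± 0.32, with its other probe at -0.55). Both had limma adjusted p = 0.048 (n = 3 per group). These were the only 2 genes called (0 higher), with 2806 at an unadjusted p under 0.05. There were 323 calls without AOM replicate 1, 2 without AOM/DSS replicate 2, 1 without AOM/DSS replicate 1, DSS replicate 2 or control replicate 2, and 0 without each of the other arrays. No gene was called with the replicate block, the authors' values or a fit of these 2 groups alone, and Wnt3 was at 0.15 with normexp on all spots. In the slide holding AOM replicate 3 and the DSS arrays, Bex4 was at -5.86 and Wnt3 at -2.35 (limma adjusted p = 0.23 and 0.38), and 1 other gene was called. Mmp7 was at -5.27 ± 0.84 and Lgr5 at -4.27 ± 0.91 (limma adjusted p = 0.098 and 0.13).

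In this direct test 0 list members passed over all genes tested. Adjusted over the list alone, 14 of 21 Wnt genes, 16 of 23 cell cycle genes and 6 of 7 mast cell markers fell (medians -1.44, -1.07 and -2.22, and -2.30, -1.18 and -2.72 within the slide). With the same adjustment 3 of 21 absorptive genes rose (median 0.84). Examples are Notum (at least 14.0-fold lower), Cdk1 (-1.50 ± 0.42), the mast cell protease Mcpt1 (-2.88 ± 0.64) and the transporter Slc6a14 (1.66 ± 0.27). Camera adjusted p = 1.7e-12, 5.7e-10, 1.6e-06 and 1.6e-06, adjusted p = 0.491, 0.645, 0.491 and 0.491 with an estimated correlation. Cytokine genes (0 of 17 alone, median -0.84, and -0.68 at the bound), metalloproteinase genes (1 of 14 fell alone, -0.94, and -0.68 at the bound), neutrophil markers (1 of 9 fell alone, -1.02) and fatty acid oxidation genes (0 of 16 alone, 0.34) were also called by camera, the first and last with medians of -1.44 and 0.56 within the slide (adjusted p = 0.0016, 0.00064, 0.0021 and 0.0051, adjusted p = 0.645, 0.645, 0.645 and 0.609 with an estimated correlation). Cxcl5 was at -2.80 ± 0.95 and the receptor Trem1 at -1.83 ± 0.34. Signs differed, without a call, for tuft (median 0.46, mean -0.14, down), antimicrobial (0.66, -0.28, up) and prostaglandin genes (0.06, -0.02, down).

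The AOM and DSS effects, each against the same 3 control arrays, correlated at r = 0.845 over 18917 genes, and 84.0% of genes had the same sign. In 100 simulations of unchanged groups sharing those controls the mean r was 0.50 and the highest 0.524. The covariance was 0.904 against a simulated 0.103. All 3 controls lie on a slide without AOM or DSS arrays, and these simulations leave slide out. The simulations also draw each gene independently, although genes vary together across these arrays. Their range is therefore too narrow to judge the observed r or covariance. With slide as a block r was 0.811, and simulated unchanged groups in that design had a mean r of 0.798 and a highest of 0.809. The covariance in that fit was 1.71, against a simulated 0.747. Of the 30 genes higher after DSS, 29 were also called higher after AOM, and of 32 lower genes 29 were also called lower; the shared controls raise such an overlap, and its size without any change was not simulated. Wfdc18 rose by 6.11 ± 0.70 and 4.16 ± 0.70 and Msln, a member of the repair epithelium list, by 1.88 ± 0.26 and 1.97 ± 0.26 log2 units (AOM and DSS; limma adjusted p under 0.05 for each).

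**Figure D5:**
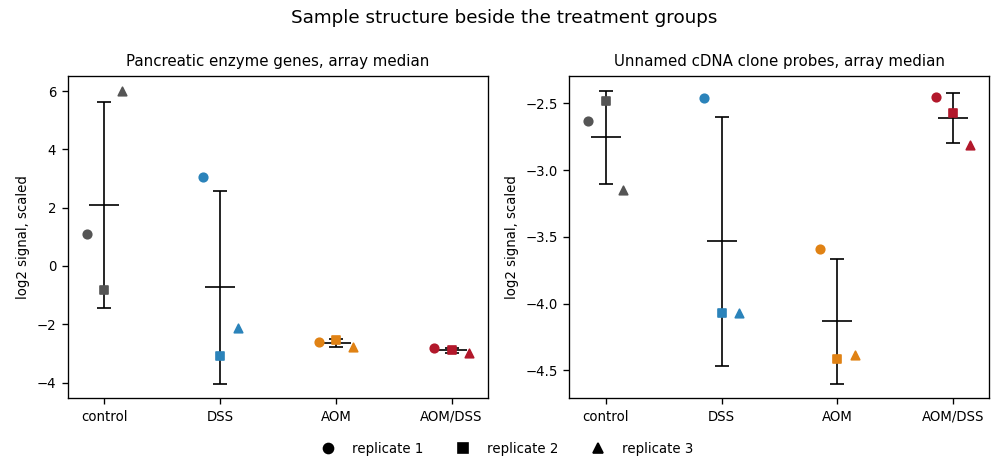
Median log2 value minus the array's 75th percentile (y axis) of 22 pancreatic genes and of 2209 cDNA clone probes on each array, by group; points are arrays and bars mean ± SD, n = 3. The pancreatic median is 6.02 on control replicate 3, and the clone median is -3.59 to -4.42 on AOM arrays and -3.14 to -2.48 on control arrays.

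Over all 192 list tests camera called 81, of which 0 remained with an estimated correlation (lowest adjusted p = 0.491, 18 with an unadjusted p under 0.05). Under median scaling the median of all genes was -0.12, 0.16, -0.36 and -0.18 log2 units in AOM/DSS against control, AOM against control, AOM/DSS against AOM and AOM/DSS against DSS, against 0.03, -0.01, -0.04 and 0.04 as reported. Under quantile normalization it was 0.12 in the last.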

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

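The tests of the 3 patterns below (Wnt genes, cDNA clone probes and pancreatic genes) were chosen only after the result was seen, with their marker lists and limits, except for the share implied by fallen genes, written before its own value but after the share from risen genes was known. Its rule was made stricter once that value was seen, which took the verdict from agreement to undecided, and for AOM replicate 1 from against to undecided. A first version of the marker lists had left out genes whose values had already been looked up; they were put back, and which pancreatic genes are also known in colon was noted then. The islet hormone genes looked up with them were left out. The regroupings of arrays were set beforehand.

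These results stand out because the effects of DSS and AOM, each against control, differ between the groups in the direct test of DSS against AOM. For single genes the fitted log2 difference was -5.10 for Bex4 and -2.71 for Wnt3 (limma adjusted p = 0.048 for both). Both were dim on the DSS arrays, so the falls are at least 10.8-fold and 1.97-fold. Neither was called with slide or replicate number as a block. Wnt3 was at 0.15 with normexp on all spots, and its other probe was at -0.55. List medians differed by -1.44 for Wnt and crypt stem cell genes, 0.84 for absorptive genes, -0.84 for cytokines (-0.68 with dim members at their bound), -0.94 for metalloproteinases (-0.68 at the bound), -1.07 for cell cycle genes, 0.34 for fatty acid oxidation genes, -1.02 for neutrophil markers and -2.22 for mast cell markers. Camera called each of these lists at its preset correlation, and with an estimated correlation adjusted p ran from 0.491 to 0.645.

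Wnt target genes were high on AOM replicates 2 and 3, and the pattern rests mainly on those 2 arrays. The median member's linear signal lay 61.1 and 59.5% of the way from the control mean to the AOM/DSS mean there. On AOM replicate 1 it was 2.04%, with a list score of -0.51 against -1.68 to -1.18 on the controls. A slide effect is argued against by a median gap of 2.30 log2 units between AOM replicate 3 and the DSS arrays on its own slide, and mislabelled AOM/DSS arrays by an enteroendocrine score 3.18 higher on the lowest AOM array than on the highest AOM/DSS array. If the AOM samples held RNA of neoplasms like those of the AOM/DSS mice, 388 risen genes imply a share of 47.0 and 44.9% in replicates 2 and 3, and 322 fallen genes one of 76.4 and 73.5%, a ratio of 0.611 in replicate 3; in replicate 1 the shares were 9.13 and 60.8%, a ratio of 0.15. Because the fallen genes gave a high share there too, they are not specific to such RNA and decide for no replicate, and lesions in the AOM tissue and a response of its epithelium to AOM cannot be told apart here. A Wnt response to repeated AOM, in lesions or outside them, therefore stays a hypothesis, and tissue counts of lesions were not used here.

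Probes for 2209 unnamed cDNA clones were low on the AOM arrays (medians -3.59, -4.42 and -4.39) and on DSS replicates 2 and 3 (-4.07 and -4.07), against -2.46 on DSS replicate 1. Slide is argued against by the gap of 1.61 log2 units between DSS replicate 1 and the nearer DSS array on its slide, and low brightness by a difference of -1.38 between AOM and control arrays although the AOM arrays were on average brighter by 0.24 log2 units in the 75th percentile. A lower share of nuclear or unspliced RNA in those samples could account for it: the median change of 7 nuclear RNAs measured of 12 listed was -2.13 in AOM against control, with 5 of them called lower. How such a difference arose, in the tissue or in its handling, was not tested.

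Pancreatic enzyme genes were high on control replicate 3, DSS replicate 1 and control replicate 1. Slide is argued against by the median gap of 5.14 log2 units between DSS replicate 1 and the other DSS arrays on its slide. Pancreatic RNA in those samples would shift all its genes alike, and the gap between control replicate 3 and DSS replicate 1 had an SD of 0.731 over the 22 genes measured (mean 2.45) and of 0.429 over the 14 not also known in colon (mean 2.75). Between control replicates 3 and 1 the SD was 2.02 over the 22 genes (mean 3.47). Over those 14 it was 1.06 (mean 4.48), just above the limit of 1. Pancreatic RNA is thus a possible source for the first 2 arrays and stays open for control replicate 1. The limit was not set against other gene sets. Control replicate 3 and DSS replicate 1 are each other's nearest arrays (r = 0.970), so their gaps may vary little in any set. Genes high on these arrays, such as Cela3b and Pnlip, differed within the control and DSS groups. Their falls after AOM and in AOM/DSS neoplasms therefore say little about the colon. Some of the 22 do not follow this pattern, such as Sycn and Klk1. Sycn was at 8.45, 8.59 and 8.49 on the controls and 7.19 to 7.55 on the DSS arrays. Klk1 was at 7.65, 7.69 and 7.49 on the controls and 6.09 to 6.96 on the DSS arrays. In AOM/DSS neoplasms they were at -1.92 to 2.19 and 0.20 to 3.24. No biological explanation was tested.

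The 6 arrays of each comparison can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. AOM/DSS against control called 6567 genes in the real split (highest other 0; 1 of the 10 splits called as many), AOM against control 6131 (highest other 1; 1 of 10), AOM/DSS against AOM 7030 (highest other 0; 1 of 10), AOM/DSS against DSS 6795 (highest other 0; 1 of 10) and DSS against AOM 2 (highest other 1; 1 of 10). DSS against control called 62, and 2 of the 10 splits called as many; the other set DSS replicate 1 and control replicates 1 and 2 against DSS replicates 2 and 3 and control replicate 3, with 798 calls. That split calls several times the real count, points to a structure of the samples, and follows the medians of the clone probes (-2.46, -2.63 and -2.48 against -4.07, -4.07 and -3.14), not the slide. For any group difference, 1 of 100 splits of the 12 arrays, the real one with 9958 genes, was as large (highest other 3530). For genes called in all 3 AOM/DSS comparisons it was 1 of 100 (2869, highest other 0). A random grouping of these 12 arrays can therefore be excluded for these 2 counts. The splits leave slide out, and those that mix AOM/DSS arrays into other groups raise the spread within groups. They cannot speak to chance between mice, since replicates may not be separate mice.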

How the results depend on the processing

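The fits with normexp on fewer spots, named genes only, the clone median as a covariate and 2 arrays left out together were chosen only after the result was seen; the other alternatives were set beforehand. Unless said otherwise, counts are of genes called in AOM/DSS against control, AOM against control, DSS against control, AOM/DSS against AOM, AOM/DSS against DSS, DSS against AOM, any group difference and all 3 AOM/DSS comparisons (6567, 6131, 62, 7030, 6795, 2, 9958 and 2869 as reported). Median scaling, a filter on all 12 arrays, the mean of a gene's probes, the variance trend and, where counted, a 2-fold threshold left every one of these counts within 1.5 times, except DSS against AOM at 0 with the filter, 1 with the mean and 1 with the trend. Signal over background limits genes dim in a group to a lower bound. In AOM/DSS against control the self-test recovered 11% of genes changed by 1 log2 unit. It made 75 calls there, against 6567 in the data, so its Benjamini-Hochberg cutoff was stricter. That percentage therefore does not measure recovery in the comparisons with far more calls. Causes below were not tested unless the setting itself gives them, such as fewer arrays or a stricter threshold.

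With slide as a block the counts were 2204, 4, 2, 2850, 437, 1, 2488 and 265. Of 716 named gene values 327 lost their call, and 0 of those called in either fit changed direction. Sign changes of values called in neither fit were not counted. The block takes 2 degrees of freedom and leaves 3 of the 6 contrasts without a shared slide. The correlation of AOM and DSS effects was 0.811, against a mean of 0.798 and a highest of 0.809 in 100 simulations of unchanged groups in that design. The covariance was 1.71, against a simulated 0.747. Genes were drawn independently in the simulations, so neither comparison can decide on a shared response. Of 81 list tests called, 69 were called with this block and 12 were not, and 12 others were called only with it. In DSS against control the Wnt list turned from 0.02 to -1.30 and the immediate early list from 0.51 to -0.21. The replicate block gave 6164, 5997, 40, 6748, 6505, 0, 9276 and 2604, and 190 of 192 list tests stayed on their side. Whether the replicate numbers pair the arrays stays undecided. Deviations of same-numbered arrays correlated from -0.27 to 0.25 (median 0.08, 18 pairs) and of others from -0.26 to 0.38 (median -0.08, 36 pairs). These ranges overlap, and 3 arrays per group are too few to rule out a weak pairing.

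Normexp on all spots gave 2736, 1870, 1, 1262, 1896, 0, 2451 and 582; on DSS replicate 2 and control replicates 1 and 2 a few spots far below their local background (10, 7 and 6) shaped the fit. Without such spots DSS against control gave 117 and DSS against AOM 0. The sign changes that follow cover only results called as reported or in the normexp fit. With all spots these changed sign: the oxidative phosphorylation list in AOM against control (0.52) and DSS against AOM (-0.27); in AOM/DSS against control Cdh5 (-0.0220), Eda2r (-0.69), Tie1 (-0.53), Ereg (-1.13), Foxp3 (-1.36; -0.26 without such spots) and Esam (-0.70). In AOM against control they were Trem1 (-0.21), Foxp3 (-0.40), Tie1 (-0.13), Itgam (-0.19), Ptgds (-0.34), Cxcl2 (-0.37), Pecam1 (-0.16) and Cd4 (-0.93). In AOM/DSS against DSS they were Eda2r (-0.27), Mmp12 (-0.42), Ereg (-0.71) and Hpgds (-0.0818), and in DSS against AOM Wnt3 (0.15). None of these genes kept a call there.

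Array weights gave 9250, 10285, 4619, 10905, 11110, 1987, 15056 and 4693. Without a filter AOM/DSS against control gave 13797, AOM/DSS against DSS 13223, DSS against control 40, DSS against AOM 0 and any difference 16422. Quantile normalization gave 111 for DSS against control and 4 for DSS against AOM, and the authors' values 111 and 0. Fits of 2 groups only gave 17 and 0, and adjusted p under 0.01 gave 3587, 1081, 7, 1869, 2668, 0, 3354 and 891. On named genes DSS against control gave 124, AOM/DSS against AOM 4618 and DSS against AOM 8. With the clone median as a covariate the counts were 5884, 1, 17, 223, 3598, 0, 4253 and 219, and the cell cycle list in AOM/DSS against AOM turned from -0.20 to 0.65 (camera adjusted p = 0.00096). Without DSS replicate 1 and control replicate 3, DSS against control gave 4277 and DSS against AOM 0, and without AOM replicate 1 and DSS replicate 1 they gave 3759 and 220.

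Leaving out each array in turn, the lowest and highest counts were 4293 (without control replicate 1) and 7364 for AOM/DSS against control, 1960 (without AOM replicate 2) and 7288 for AOM against control, and 1 (without DSS replicate 2) and 3181 (without DSS replicate 1) for DSS against control. They were 3365 (without AOM/DSS replicate 1) and 8082 for AOM/DSS against AOM, 3318 (without DSS replicate 3) and 8855 for AOM/DSS against DSS, 0 and 323 (without AOM replicate 1) for DSS against AOM, 5921 and 11608 for any difference, and 1485 and 3405 for all 3 comparisons. List tests called ran from 76 to 86. The correlation of AOM and DSS effects was recomputed only without each control array. It ran from 0.826 (without control replicate 1, simulated mean 0.60) to 0.884 (without control replicate 3, also 0.60). How it depends on single AOM or DSS arrays was not computed. Of 81 list tests called, 0 remained with an estimated correlation (18 of 192 had an unadjusted p under 0.05), and fry called 56.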

Other observations

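The genes and lists in this part were chosen only after the result was seen, and their tests with them.

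None of the gene lists covered the circadian clock. Of 19 clock genes measured, 3 rose, 11 fell and 5 did not pass in AOM/DSS against control, 2 rose, 10 fell and 7 did not pass in AOM against control, and 4 fell and 15 did not pass in DSS against control. In AOM/DSS, AOM and DSS against control, the output factor Dbp was at -4.61, -1.69 and -2.85 log2 units, its relative Tef at -2.77, -1.54 and -1.69, and the period gene Per3 at -2.71, -2.49 and -2.76, each with a limma adjusted p under 0.05 (n = 3 per group). The repressor Ciart was at least 12.9-fold lower in AOM/DSS, at -2.63 in AOM and at least 6.67-fold lower in DSS, also with an adjusted p under 0.05. Nfil3, a repressor of Dbp targets that peaks at another time of day, was at 1.91, 1.40 and 1.28, with limma adjusted p = 0.073 in DSS against control. The time of day of collection is not given in the sources used here.

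Of 7 nuclear RNAs measured, 5 fell after AOM and 2 did not pass: Malat1, a nuclear speckle RNA, was at -2.21 ± 0.62 log2 units, Neat1, the scaffold of paraspeckles, at -2.50 ± 0.68 and the X inactivation RNA Xist at -2.13 ± 0.48 (limma adjusted p = 0.024, 0.021 and 0.013, n = 3 per group). Airn and Tug1 also fell, while Meg3 and Kcnq1ot1 were at 0.28 and -1.61 (limma adjusted p = 0.84 and 0.078). None of the 7 was called in DSS against control, but Neat1 was at 2.99 and 2.96 on DSS replicates 2 and 3 against 2.43 to 3.62 on the AOM arrays, and Xist at 2.49 and 2.81 against 2.15 to 2.76. In AOM/DSS against AOM Malat1, Neat1 and Xist were at 1.91 ± 0.62, 2.28 ± 0.68 and 1.96 ± 0.48.

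Markers of stroma varied among the controls: the macrophage score was -1.75, -2.91 and -0.35 and the endothelial score -2.25, -1.99 and 0.44 on control replicates 1, 2 and 3. B and plasma cell scores were 2.51, 0.93 and -0.66 on AOM replicates 1 to 3, 1.45, 2.22 and 1.38 on DSS replicates 1 to 3, and -2.34, -3.45 and -1.57 on AOM/DSS replicates 1 to 3.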
